A study of Mus musculus with 22 samples.

How the data were processed

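Total RNA from mouse liver and liver tumors was sequenced in 17 libraries, and open chromatin was mapped in 5 libraries by Omni-ATAC, in which a transposase cuts accessible DNA of isolated nuclei. The RNA was extracted with Trizol and chloroform from fresh or frozen tissue, per the labels' protocols, so each library holds all cell types of the piece of tissue. Groups were taken from the labels. They were 4 tumors of a mouse on doxycycline (YAP1on tumors), 4 tumors of a mouse taken off doxycycline for 6 days (day 6 tumors), 3 hbHep mice at days 121, 114 and 117, and 3 mice without a working Fah gene that were kept on NTBC (FAH liver). The labels give 1 mouse code for each tumor group, so mouse and treatment cannot be told apart between tumors. The model used below pools the spread between tumors of 1 mouse with that between mice. The ATAC libraries were 1 each of YAP1on tumor, days 14, 33 and 64 without YAP1, and liver labeled WT, not FAH.

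The authors deposited the RNA values as a signal per gene and library, in a unit read here as scaled reads per base, made with bcl2fastq, kallisto 0.45.0 and sleuth on GRCm38.p6, per the submitters' processing notes. Versions of bcl2fastq and sleuth are not given in the sources used here. The table held 36555 Ensembl genes, of which 35912 matched a symbol. kallisto shares reads among similar transcripts by estimation, so values within the Mup, Serpina1, Cyp2, Cyp3a, Cyp4a12 and Gsta families and their pseudogenes are uncertain for a single member, and Mup9 and 1 unnamed gene held identical values. Low values were whole multiples of the value of 1 read (tolerance 0.02) in 42.2 to 54.9% of cases, so whole reads were not recovered and no count model was used. From the smallest common step of low values, depth was estimated at about 17.2 to 32.2 M reads per library, with M for the metric prefix mega (24.2 to 32.2 M in YAP1on tumors, 23.2 to 27.9 M in day 6 tumors, 17.2 to 21.7 M in each hbHep library, 20.5 to 29.2 M in FAH liver). The ATAC intervals and the score beside each were deposited by the authors as lists per library on mm10, made with bcl2fastq, cutadapt, BWA, SAMtools and Picard, per the submitters' processing notes; the program and rule that made the intervals, and any shift of read ends, are not given in the sources used here. The score of the YAP1on list is a whole number and the fifth column of the other 4 lists could not be read as a value, so no score was compared.

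The 2 technical libraries of each hbHep mouse were averaged and counted as 1, which left 14 samples. Values were rescaled by median-of-ratios factors (0.9585 to 1.095), called abundance from here on. A gene was tested if its abundance was at least 10 in at least 3 samples, which kept 17958 genes. Tests were made on log2(abundance + 1) with limma 3.58.1 (lmFit, and eBayes with a trend) in R 4.3.3, in 1 model of the 4 groups without covariates, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on this log2(abundance + 1) scale, which understates changes of low genes. Yap1, Ctnnb1 and Fah were also compared by exact permutation tests, two-sided. Standard errors and p-values are limma's unless another test is named.

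The tests, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined. The 32 lists were YAP1 target genes, beta-catenin and pericentral genes, periportal hepatocyte genes, hepatocyte transcription factors, hepatocyte secreted proteins, cytochrome P450 and drug metabolism, urea cycle and ammonia handling, bile acid synthesis and transport, tyrosine and phenylalanine catabolism, gluconeogenesis and glycogen, glycolysis and glutamine use, fatty acid oxidation and ketogenesis, cholesterol synthesis, fetal liver and hepatoblastoma genes, cholangiocyte and liver progenitor genes, G2/M and mitosis genes, S phase genes, p53 targets and senescence genes, NRF2 and oxidative stress genes, ER stress genes, acute phase genes, interferon response genes, markers of macrophages and Kupffer cells, of T, NK and B cells, of neutrophils and of endothelial cells, stellate cell, fibroblast and matrix genes, red blood cell precursor genes, sex-biased mouse liver genes, ribosomal protein genes, circadian clock genes and Hippo pathway components. Some genes stand in several lists: Glul, Oat and Rhbg, for example, are in the pericentral and the urea cycle list. Each list was tested with limma's camera at a preset correlation of 0.01, again with an estimated correlation, and with fry, adjusted over the 128 tests of 32 lists and 4 comparisons. camera asks whether a list moved relative to the other genes; fry asks only whether its members moved, on balance, one way. Camera with a preset correlation passed 25, 20, 23 and 22 lists in the order of the comparisons below. With an estimated correlation it passed 0 in each (lowest adjusted p 0.0747), while 11, 1, 6 and 4 had an unadjusted p under 0.05, and fry passed 23, 22, 25 and 27. Every list p printed without further words is the adjusted p with the preset correlation.

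Named genes were, for each comparison, Yap1, Ctnnb1 and Fah, then the 5 largest rises and 5 largest falls among genes past the threshold whose groups did not overlap and whose level in the higher group was above the median (unnamed clones, antigen receptor segments and pseudogene symbols left out), then from each passing list the 3 members with the largest fold in the list's direction and the most abundant member, up to 30 genes. Other list members, and any gene named outside this rule, were chosen as examples after their values were seen. Positions come from the RefSeq annotation of the mouse build GRCm38 (mm10). Some genes that the rule or the lists name are not reported here; they were kept in every test and count. H19, Meg3, Rian, Mirg, Xist, Ahsp and Tf were on the lists and not analysed here.

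Intervals were compared with bedtools 2.31.1, Python 3.11.15, numpy 2.4.6 and pandas 2.3.3, by the Jaccard index of covered length and by the share of intervals overlapping another library by at least 1 bp, beside the same share after moving the intervals by 100 kb. Since the annotation used here had no strand, windows of 1 kb on each side of both gene ends stood in for the planned windows at start sites. They held an interval for 81.2 to 83.5% of the 16663 tested genes with a position, whatever the library, so a further measure was added after seeing the data: the share of the gene and 10 kb on each side covered by intervals, divided by the mean of all tested genes in the library. A list's mean was ranked among 10000 random lists of the same size matched on mean expression. With 1 library per group there is no replicate and no test of ATAC values.

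Gene and list tests were run on 17958 independent simulated genes, 100 changed 2-fold and 100 4-fold. For day 6 against YAP1on tumors, 61% of the 2-fold and 91% of the 4-fold changes were recovered with 12 false calls; for hbHep against YAP1on tumors, 61% and 91% with 5; for hbHep against FAH liver, 56% and 89% with 15; for YAP1on tumors against FAH liver, 54% and 91% with 10. Each time the moved list and 0 others of 32 were called, which cannot test list calls on correlated genes. Interval calculations gave the known answer in 7 of 7 simulations. Alternatives were a pseudocount 5 times smaller or larger, no filter on low values, values as deposited, trimmed-mean scaling (own code in place of the planned package), quantile normalization, only the 2 groups compared, no trend, only the first library of each hbHep mouse, the replicate number as a block, leaving out each replicate, and a fold change of at least 2; for ATAC, intervals of at least 200 bp, chromosomes 1 to 19 and X, an overlap of at least 50% of the interval, the same number of intervals (571061) drawn from each library, windows of 2.5 kb and, added after seeing the data, surroundings of 2 kb and no scaling to the library. Plots were drawn with matplotlib 3.10.9.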

Results

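The study followed mouse hepatoblastoma, a liver cancer of early childhood in humans, after its driver YAP1 was switched off by taking away doxycycline. RNA was measured in 4 tumors with YAP1 on, 4 tumors 6 days after YAP1 was switched off, 3 mice carrying hbHep at days 114 to 121, and liver of 3 FAH mice. By the series' title hbHep are hepatocyte-like cells that arise from tumor cells without YAP1. The hbHep mice and the liver mice both carry a deletion of exon 5 of Fah, the last enzyme of tyrosine breakdown; such mice are kept alive by NTBC, a drug that blocks an earlier step of the pathway. The tumor mice are of another strain background, so strain, and possibly sex, differs between tumors and the other 2 groups. The 10 most abundant genes took 12.2 to 25% of the signal, and 21065 to 25605 genes lay above 0. Mitochondrial genes took 5.27 to 9.11% in YAP1on tumors, 7.23 to 8.4% in day 6 tumors, 3.36 to 4.49% in hbHep and 3.56 to 3.84% in FAH liver.

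The 4 groups stood apart. On the first principal component of the 14 samples (60.7% of the variance), YAP1on tumors lay at 90.61 to 97.07, day 6 tumors at 55.81 to 65.46, hbHep at -71.91 to -61.86 and FAH liver at -148.4 to -130.06. Technical libraries of 1 hbHep mouse correlated across genes at 0.9766 to 0.9814 and libraries of different hbHep mice at 0.9569 to 0.9738. Single genes could still differ widely within a technical pair: Igf2 was 474.1 and 4326 in mouse 1, and Afp was 6538 and 603.4 in mouse 3. The hbHep levels of these genes are uncertain for that reason.

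**Figure D1:**
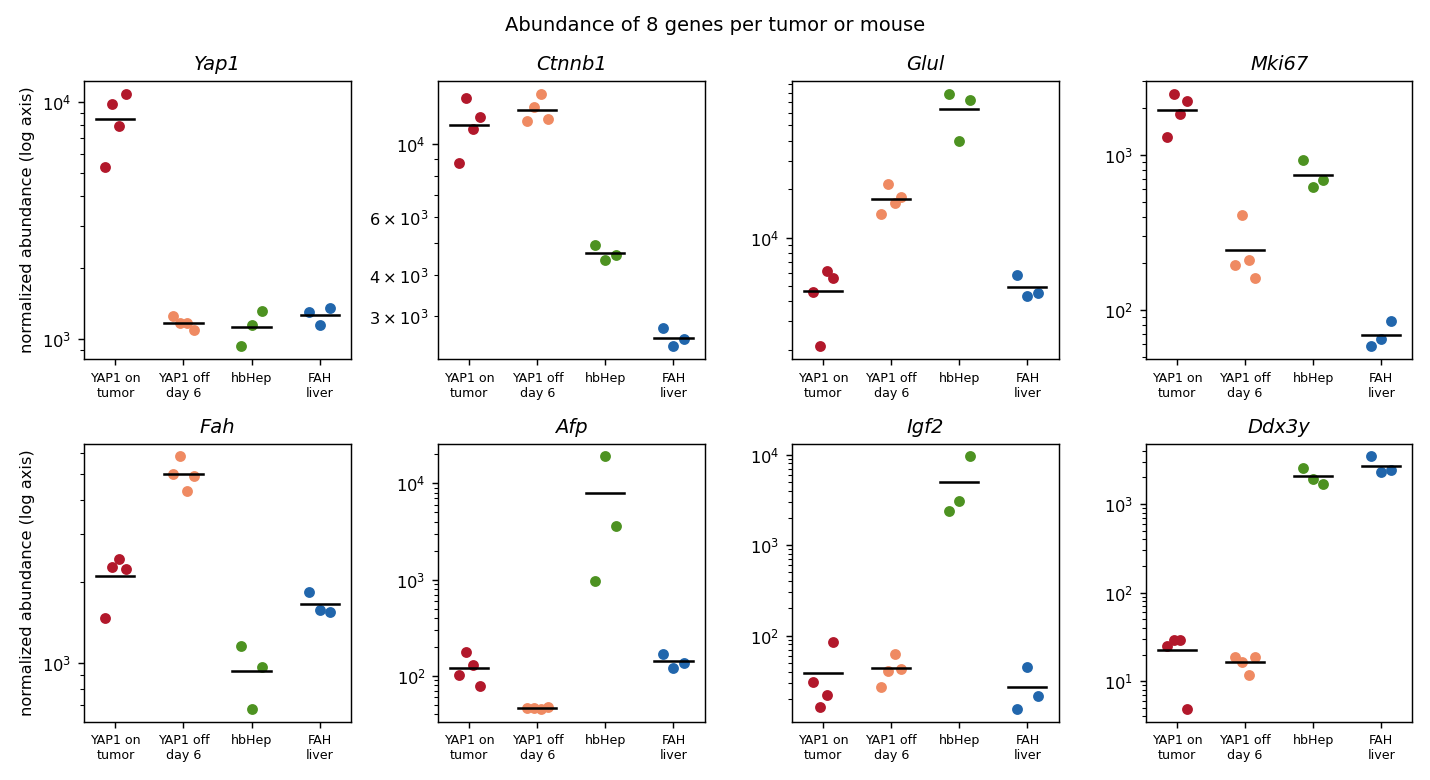
Abundance of 8 genes (log axis, rescaled reads per base) in each tumor or mouse; points are tumors or mice and bars are group means. Yap1 is high in the 4 YAP1on tumors only, Mki67 falls from a mean of 1964 to 244.5 at day 6 and stands at 747.2 in hbHep, Glul reaches 63680 in hbHep, and Afp and Igf2 vary widely among the 3 hbHep mice.

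The first comparison asked what 6 days without YAP1 changed in the tumors. Yap1 (ENSMUSG00000053110, chromosome 9, 7931999 to 8004638), the coactivator that the Hippo kinases restrain, was 8444 ± 2420 in YAP1on tumors and 1171 ± 64.3 at day 6 (SD, n = 4 each). It fell 6.97-fold (log2 fold change -2.80, SE 0.18, limma adjusted p = 5.76e-08, exact permutation p = 0.0286, the smallest that 4 against 4 allow). Ctnnb1 (ENSMUSG00000006932, chromosome 9, 120933400 to 120960507), which encodes beta-catenin, showed no difference larger than the spread between tumors (11440 ± 2100 and 12720 ± 1140, log2 fold change 0.17, adjusted p = 0.425, exact permutation p = 0.343). Fah (ENSMUSG00000030630, chromosome 7, 84585159 to 84605942) rose from 2097 ± 426 to 5032 ± 607 (2.43-fold, SE 0.18 on the log2 scale, adjusted p = 6.66e-05, exact permutation p = 0.0286). Of 17958 genes tested, 2296 were higher and 1952 lower at day 6, 795 and 949 of them by at least 2-fold. Each tumor group came from 1 mouse, so these counts compare tumors of 2 mice.

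Genes of cell division fell. All 26 G2/M and mitosis genes were lower at day 6 (26 adjusted over the list alone, median log2 fold change -2.91, p = 6.2e-35, adjusted p = 0.0747 with an estimated correlation). Ccnb2 (ENSMUSG00000032218, chromosome 9, 70407689 to 70421554), a cyclin that drives entry into mitosis, was 625.4 ± 131 in YAP1on tumors and 26.91 ± 12.4 at day 6 (n = 4 each, log2 fold change -4.55, SE 0.30, adjusted p = 9.27e-08). Mki67 (ENSMUSG00000031004, chromosome 7, 135689784 to 135716450), a marker of cycling cells, was 1964 ± 516 and 244.5 ± 114 (8.32-fold lower, adjusted p = 7.49e-07). Ccnb1 fell from 384.9 to 25.39, Cdc20, an activator of the anaphase promoting complex, from 209 to 12.9, and Depdc1a from 272 to 10.04. Of 26 S phase genes 22 fell and 2 rose (24 and 2 adjusted over the list alone, median -1.11, p = 5.93e-14, adjusted p = 0.207 with an estimated correlation). Uhrf1 (-2.52), the replication helicase subunit Mcm5 (-2.33) and the licensing factor Cdc6 (-2.32) were among those that fell; E2f8, a repressor of the E2F family, rose from 690.6 ± 125 to 2122 ± 236.

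The YAP1 program fell in part. Among 25 YAP1 target genes 16 fell and 3 rose (16 and 3 adjusted over the list alone, median log2 fold change -1.17, p = 7.22e-07, adjusted p = 0.207 with an estimated correlation). Ccn2 (ENSMUSG00000019997, chromosome 10, 24595442 to 24598683), a matrix protein induced directly by YAP1, was 5.6-fold lower at 457.6 against 2564 (SE 0.14 on the log2 scale, adjusted p = 2.09e-08). Ankrd1, an ankyrin repeat protein, was at -2.50 and the growth factor Areg at -2.84. The 3 that rose were Nt5e (0.67), Igfbp3 (0.65) and Dock5 (0.37). Of 20 Hippo pathway components 8 fell and 1 rose (9 and 1 adjusted over the list alone, p = 0.00062, adjusted p = 0.25 with an estimated correlation). Yap1 itself and its DNA binding partner Tead4 (-1.81) fell, and the kinase adaptor Mob1b (0.31) rose. Psca (ENSMUSG00000022598, chromosome 15, 74714839 to 74717065), a surface protein, was 752.5 ± 206 with YAP1 on and 1.125 ± 1.3 at day 6 (log2 fold change -8.67, SE 0.65), the largest fall by the rule for named genes. The mucin Muc13 went from 1005 to 38.45 and the glutathione transferase Gsta1 from 313.2 to 7.482.

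Hepatocyte genes rose at the same time. All 12 genes of tyrosine and phenylalanine catabolism were higher at day 6 (12 adjusted over the list alone, median log2 fold change 1.23, p = 1.61e-10, adjusted p = 0.207 with an estimated correlation). Gnmt (2.03), Hgd (1.94) and Hpd were among them; Hpd, the enzyme that NTBC blocks, went from 6354 ± 1110 to 21730 ± 1980. For cytochrome P450 and drug metabolism 25 of 32 rose and 0 fell (27 and 2 adjusted over the list alone, median 1.39, p = 3.05e-13, adjusted p = 0.24 with an estimated correlation). The carboxylesterase Ces3a stood at 3439 against 173.4 and Cyp2c54 at 3205 against 384.6. Bile acid genes rose in 17 of 20 and fell in 0 (18 and 0 adjusted over the list alone, median 1.38, p = 3.04e-14, adjusted p = 0.207 with an estimated correlation). Slc10a1 (ENSMUSG00000021135, chromosome 12, 80953185 to 80968705), the transporter that takes bile acids up from blood, rose from 1127 ± 355 to 8373 ± 2060 (SE 0.27 on the log2 scale, adjusted p = 1.64e-06). The bile salt export pump Abcb11 rose from 7115 to 28500, the bile acid ligase Slc27a5 from 1143 to 6727 and Cyp8b1 from 735.1 to 3772. Cholesterol synthesis rose in 19 of 20 genes (19 adjusted over the list alone, median 1.29, p = 1.71e-14, adjusted p = 0.25 with an estimated correlation). Hmgcs1 (ENSMUSG00000093930, chromosome 13, 119690351 to 119708260), an early enzyme of the pathway, went from 8911 ± 2210 to 31380 ± 2780 (SE 0.21, adjusted p = 9.94e-06). Sc5d went from 4752 to 19370 and Idi1 from 1057 to 3617.

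Zonal genes of hepatocytes rose unevenly. Of 24 beta-catenin and pericentral genes 16 rose and 1 fell (17 and 1 adjusted over the list alone, median log2 fold change 1.25, p = 3.98e-11, adjusted p = 0.207 with an estimated correlation). Oat, ornithine aminotransferase, rose by 3.12, Cyp1a2 by 2.07, and Glul (ENSMUSG00000026473, chromosome 1, 153899929 to 153909723), the pericentral glutamine synthetase, from 4613 ± 1810 to 17470 ± 3150. The general beta-catenin targets Axin2 (0.31) and Nkd1 (0.35) did not pass, and Tnfrsf19 fell (-0.69). Among 20 periportal genes 8 rose and 2 fell, Sdsl (-1.66) and Hsd17b13 (-1.43), with 10 and 2 adjusted over the list alone (median 0.54, p = 0.0189, adjusted p = 0.476 with an estimated correlation). Cyp2f2 (1.95), Ass1 (1.86) and Cps1 (1.68), the first enzyme of the urea cycle, were higher. The urea cycle list had 11 of 13 genes higher and 0 lower (12 and 0 adjusted over the list alone, median 1.36, p = 5.13e-09, adjusted p = 0.207 with an estimated correlation). Hepatocyte transcription factors rose in 8 of 22 (11 adjusted over the list alone, p = 0.000119, adjusted p = 0.342 with an estimated correlation), among them Nr0b2 (1.90), Nr1i3 (1.63) and Cebpa (0.86). Secreted proteins rose in 11 of 27 (11 adjusted over the list alone, p = 1.07e-06, adjusted p = 0.369 with an estimated correlation). Serpina3k (2.70) and Apoa2 (2.43) led, while Alb was at -0.41 and did not pass.

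Gluconeogenesis and glycogen had 8 of 15 genes higher (8 higher and 2 lower adjusted over the list alone, p = 0.00734, adjusted p = 0.428 with an estimated correlation), the glycogen synthase Gys2 by 1.05. Fatty acid oxidation had 8 of 20 higher (9 adjusted over the list alone, p = 0.000674, adjusted p = 0.428 with an estimated correlation), with Acaa1b at 1.45. Quantile normalization ended the calls of these 2 lists (adjusted p = 0.317 and adjusted p = 0.208), of the periportal list (adjusted p = 0.159), of secreted proteins (adjusted p = 0.0557) and of endothelial markers (adjusted p = 0.0734). Mup genes encode major urinary proteins made by mature hepatocytes. Mup22 (ENSMUSG00000110439, chromosome 4, 60817586 to 60821597) rose from 9.881 ± 3.68 to 15230 ± 6710 (log2 fold change 10.38, SE 0.82). Mup9 rose from 3.62 to 2426 and Mup10 from 0.274 to 509, while Mup16 was listed at 0 in the 4 YAP1on tumors and averaged 226.8 at day 6. Sex-biased liver genes rose in 12 of 20 and fell in 0 (13 and 1 adjusted over the list alone, median 1.87, p = 1.65e-08, adjusted p = 0.0747 with an estimated correlation). The leading members, Cyp3a44 (6.51), A1bg (4.64), Cyp2b13 (4.64) and Sult2a1 (4.47), are known as female-biased hepatocyte genes, and Y-linked Ddx3y stayed low in both tumor groups (22.26 ± 11.8 and 16.39 ± 3.25).

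Markers of ducts, fetal liver and other cell types moved with these groups. Of 23 cholangiocyte and progenitor genes 12 fell and 0 rose (14 and 1 adjusted over the list alone, median log2 fold change -0.95, p = 1.24e-06, adjusted p = 0.25 with an estimated correlation). Spp1 (ENSMUSG00000029304, chromosome 5, 104435111 to 104441053), which encodes osteopontin, was at -3.36, the duct keratin Krt7 at -1.81 and Sox9 at -1.35. Fetal liver and hepatoblastoma genes fell in 6 of 21, with Igf2bp1 at -3.77 and Gpc3 at -3.37 (6 adjusted over the list alone, p = 0.000244, adjusted p = 0.207 with an estimated correlation). Macrophage markers fell in 6 of 21, with Cd163 at -1.77 (11 adjusted over the list alone, p = 9.19e-05, adjusted p = 0.393 with an estimated correlation). Stellate cell, fibroblast and matrix genes fell in 11 of 25, with Acta2 at -1.94 and Timp1 at -1.92 (11 lower and 1 higher adjusted over the list alone, p = 0.000412, adjusted p = 0.393 with an estimated correlation). Markers of T, NK and B cells rose in 6 of 20, Cd8b1 by 1.54 (9 adjusted over the list alone, p = 0.001, adjusted p = 0.289 with an estimated correlation). Interferon response genes rose in 14 of 26, Cxcl10 by 1.76 (15 adjusted over the list alone, p = 6.06e-06, adjusted p = 0.313 with an estimated correlation). Endothelial markers rose in 5 of 20 (5 adjusted over the list alone, p = 0.0157, adjusted p = 0.55 with an estimated correlation). That call was lost without day 6 tumor 2 (adjusted p = 0.0762) or YAP1on tumor 2 (adjusted p = 0.066), and with fry (adjusted p = 0.0883). Ribosomal protein genes fell in 12 of 25 (22 adjusted over the list alone, p = 3.83e-07, adjusted p = 0.393 with an estimated correlation). p53 targets fell in 6 of 20, Cdkn1a (-1.07) among them, and rose in 2, Bbc3 (1.54) among them (8 and 2 adjusted over the list alone, p = 0.0397, adjusted p = 0.466 with an estimated correlation). The p53 call was lost without day 6 tumor 2 (adjusted p = 0.0701) or YAP1on tumor 3 (adjusted p = 0.0608), and with fry (adjusted p = 0.0563).

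The remaining 7 lists did not pass at day 6. They were glycolysis and glutamine use (adjusted p = 0.225), NRF2 genes (adjusted p = 0.598), ER stress genes (adjusted p = 0.0713), acute phase genes (adjusted p = 0.188), neutrophil markers (adjusted p = 0.966), red blood cell precursor genes (adjusted p = 0.307) and circadian clock genes (adjusted p = 0.222). ER stress genes passed without the filter on low values (adjusted p = 0.0141), with only the 2 groups (adjusted p = 0.0492) and without YAP1on tumor 3 (adjusted p = 0.0329). Single members did change, such as Tpi1 (0.54) and Eno1 (-0.63) in glycolysis, Hyou1 (0.79) in the ER stress list and A2m (-3.14) and Crp (1.37) in the acute phase list. So did Itgam (-1.36) among neutrophil markers, Klf1 (0.53) in the red blood cell list and Per1 (-1.80) among clock genes.

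**Figure D2:**
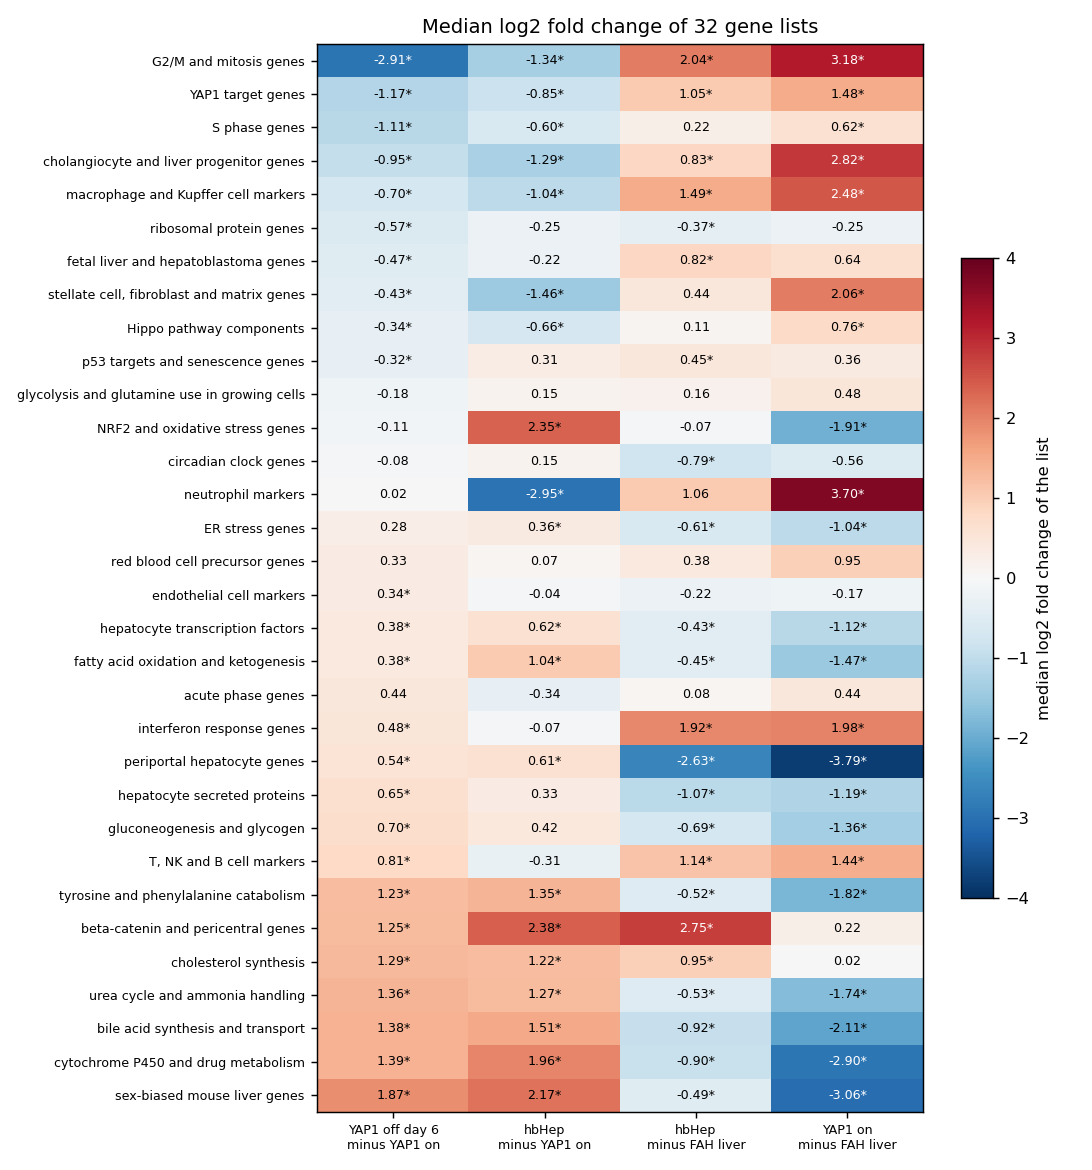
Median log2 fold change (color scale) of 32 gene lists in the 4 comparisons; an asterisk marks a camera adjusted p under 0.05 with the preset correlation, and none of the calls held with an estimated correlation. Mitosis genes are at -2.91 in day 6 against YAP1on tumors and at 2.04 in hbHep against FAH liver, while periportal genes are at -2.63 in hbHep against FAH liver.

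The second comparison asked how far hbHep were from the tumors. Yap1 was 1130 ± 189 in hbHep (n = 3) and 8444 ± 2420 in YAP1on tumors (n = 4), 7.28-fold lower (log2 fold change -2.86, SE 0.19, limma adjusted p = 1.65e-08, exact permutation p = 0.0286). Ctnnb1 was 4670 ± 259, 2.42-fold lower than in tumors (SE 0.15 on the log2 scale, adjusted p = 3.43e-06, exact permutation p = 0.0286). Fah was lower too, 929.4 ± 240 against 2097 ± 426 (adjusted p = 8.79e-05, exact permutation p = 0.0286), but reads from the deleted gene of the host may still be counted, so its level does not check the labels. Of 17958 genes 5155 were higher and 4751 lower in hbHep, 2516 and 2516 of them by at least 2-fold. Strain differs between these groups, so extremes such as the ribosomal protein gene Rps3a2 (4228 against 1.436) or the histone gene Hist1h4m (0.6519 against 788.2) cannot be put down to the tumor state.

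Pericentral genes were far higher in hbHep. Of 24 beta-catenin and pericentral genes 22 rose and 0 fell (22 adjusted over the list alone, median log2 fold change 2.38, p = 1.15e-10, adjusted p = 0.207 with an estimated correlation). Oat (ENSMUSG00000030934, chromosome 7, 132557475 to 132576398) was 144500 ± 38100 against 6072 ± 1790 (SE 0.28, adjusted p = 5.34e-09). The ammonium transporter Rhbg (ENSMUSG00000104445, chromosome 3, 88242874 to 88254739) was 11810 ± 3000 against 228.1 ± 77.5 (SE 0.25, adjusted p = 1.88e-10). Cyp1a2 (ENSMUSG00000032310, chromosome 9, 57676937 to 57683655), which metabolizes caffeine, was 61690 ± 6600 against 1778 ± 420 (SE 0.20, adjusted p = 5.2e-11). Cyp2e1 (ENSMUSG00000025479, chromosome 7, 140763819 to 140774990), an ethanol oxidizing enzyme, was 172700 ± 64600 against 70490 ± 13900 (adjusted p = 0.00661). Nkd1 (4.02), Glul (3.84) and Lef1 (3.49) rose as well. Drug metabolism genes rose in 26 of 32 and fell in 0 (27 adjusted over the list alone, p = 9.82e-11, adjusted p = 0.25 with an estimated correlation). Cyp2a5 stood at 127900 against 1851 and Ces3a at 9234 against 173.4. Largest among the rises by the rule were Cyp4a12b (8950 ± 1970 against 5.22 ± 3.98), Cyp4a12a (10220 against 8.039), Mup17 (3141 against 0.2491) and Mup9 (9352 against 3.62). The 2 Cyp4a12 genes are known as male-biased fatty acid hydroxylases.

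Liver metabolism was higher along several lists. Urea cycle genes rose in 9 of 13, with Oat, Rhbg and Glul in the lead, and only Glud1 fell (10 and 1 adjusted over the list alone, p = 6.38e-05, adjusted p = 0.28 with an estimated correlation). Bile acid genes rose in 17 of 20 (18 adjusted over the list alone, median 1.51, p = 1.36e-07, adjusted p = 0.268 with an estimated correlation). Cyp7b1, an oxysterol hydroxylase, was at 1972 against 157.5, Slco1a1 at 724.9 against 83.72, Slc27a5 at 9032 against 1143 and the uptake transporter Slco1b2 at 44560 against 6588. Tyrosine catabolism rose in 10 of 12 and only Fah fell (10 and 1 adjusted over the list alone, p = 0.000223, adjusted p = 0.313 with an estimated correlation). Fatty acid oxidation rose in 15 of 20, Acaa1b by 3.72 (15 adjusted over the list alone, p = 5.2e-06, adjusted p = 0.322 with an estimated correlation). Cholesterol synthesis rose in 18 of 20, Fdps by 1.92 (18 adjusted over the list alone, p = 5.62e-06, adjusted p = 0.391 with an estimated correlation). NRF2 and oxidative stress genes rose in 19 of 22 and Akr1b8 (-0.70) fell (19 and 1 adjusted over the list alone, median 2.35, p = 1.25e-07, adjusted p = 0.296 with an estimated correlation). The glutathione transferase Gsta2 was at 9342 against 341.8 and the efflux pump Abcc4 at 13090 against 680.9. Gstm1 was at 99400 ± 9070 against 20720 ± 3720 and the cystine transporter Slc7a11 at 4918 ± 6900 against 133.5 ± 16. Nr1i3 (3.22) and Cebpa (1.95) rose and Onecut1 (-1.30) fell among hepatocyte transcription factors, of which 14 of 22 rose and 2 fell (14 and 2 adjusted over the list alone, p = 0.00281, adjusted p = 0.43 with an estimated correlation).

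Periportal genes rose in 10 of 20 and fell in 3, with Etnppl at 4.41, Cyp2f2 at 3.35 and Mup20 at -2.20 (11 and 3 adjusted over the list alone, median 0.61, p = 0.028, adjusted p = 0.503 with an estimated correlation). This call was lost without hbHep mouse 3 (adjusted p = 0.13), with the first technical libraries only (adjusted p = 0.36) and under quantile normalization (adjusted p = 0.159). Quantile normalization also ended the calls of transcription factors (adjusted p = 0.0865) and ER stress genes (adjusted p = 0.417). ER stress genes rose in 8 of 19, Asns by 3.54 (8 adjusted over the list alone, p = 0.0201, adjusted p = 0.473 with an estimated correlation). Sex-biased genes rose in 12 of 20 and fell in 7 (12 and 7 adjusted over the list alone, p = 0.0202, adjusted p = 0.28 with an estimated correlation). Y-linked Eif2s3y (7.53) and Ddx3y (6.70) were higher in hbHep, and the female-biased gene Cyp2b9 (-7.23) was lower.

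Mitosis, S phase and YAP1 target genes were lower in hbHep than in tumors, and so were markers of ducts, neutrophils, macrophages and matrix. Mitosis genes fell in 24 of 26 (24 adjusted over the list alone, median log2 fold change -1.34, p = 3.21e-07, adjusted p = 0.287 with an estimated correlation). The cyclin Ccna2 was at 193.4 ± 34.9 against 668.5 ± 135, Foxm1, a transcription factor of mitotic genes, at 41.2 against 187.1, and Bub1b at 22.06 against 83.26. S phase genes fell in 14 of 26 and Chaf1a rose (14 lower and 2 higher adjusted over the list alone, p = 0.00556, adjusted p = 0.443 with an estimated correlation). YAP1 targets fell in 14 of 25 and rose in 3, with Ankrd1 at -4.90, Ccn2 at -2.70 and Nt5e at 2.32 (14 and 4 adjusted over the list alone, p = 0.00203, adjusted p = 0.268 with an estimated correlation). Hippo components fell in 13 of 20, with Vgll3 at -5.73 (13 lower and 1 higher adjusted over the list alone, p = 0.000579, adjusted p = 0.25 with an estimated correlation). Cholangiocyte genes fell in 14 of 23 and rose in 2, with Spp1 at -5.03, Sox9 at -3.55 and Krt23 at 1.45 (15 and 2 adjusted over the list alone, p = 0.00022, adjusted p = 0.322 with an estimated correlation). All 13 neutrophil markers fell, with Retnlg at -4.28 and S100a8 at -3.57 (13 adjusted over the list alone, p = 1.07e-05, adjusted p = 0.287 with an estimated correlation). Macrophage markers fell in 13 of 21 and Gpnmb rose by 2.95 (14 and 1 adjusted over the list alone, p = 0.00216, adjusted p = 0.49 with an estimated correlation). Matrix genes fell in 17 of 25, with Lox at -4.31 and Col1a1 at -2.95 (18 adjusted over the list alone, p = 1.32e-06, adjusted p = 0.296 with an estimated correlation). Other large falls by the rule were Gvin1, an interferon-inducible GTPase (8.046 against 1837), Psca (5.046 against 752.5), Cfap44 (0.8659 against 314.1) and Serpina1e (47.03 against 6113).

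The fetal list did not move one way in hbHep against tumors (7 of 21 higher, 6 lower, 7 and 6 adjusted over the list alone, adjusted p = 0.866, median log2 fold change -0.22, mean 0.68). Igf2 (ENSMUSG00000048583, chromosome 7, 142650768 to 142666816), a fetal growth factor, rose by 6.99. Afp (ENSMUSG00000054932, chromosome 5, 90490714 to 90508907), which encodes alpha-fetoprotein, rose by 5.10 and the imprinted Dlk1 by 4.32, while Igf2bp1 (-3.91) and Gpc3 (-3.31) fell. Among the other 11 lists without a call were secreted proteins (adjusted p = 0.358), gluconeogenesis (adjusted p = 0.109), glycolysis (adjusted p = 0.254), p53 targets (adjusted p = 0.66), acute phase genes (adjusted p = 0.3) and interferon response genes (adjusted p = 0.891, median -0.07, mean 0.06). Nor did markers of T, NK and B cells (adjusted p = 0.345), endothelial markers (adjusted p = 0.456), ribosomal protein genes (adjusted p = 0.112), clock genes (adjusted p = 0.724, median 0.15, mean -0.03) or red blood cell genes (adjusted p = 0.358, median 0.07, mean -0.55). Gluconeogenesis passed without the filter (adjusted p = 0.042), without hbHep mouse 2 (adjusted p = 0.04) and with fry (adjusted p = 0.00287), and glycolysis with fry (adjusted p = 0.0262). Ribosomal protein genes passed under quantile normalization (adjusted p = 1.15e-05) and without YAP1on tumor 4 (adjusted p = 0.00482), and acute phase genes under quantile normalization (adjusted p = 0.0265).

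The third comparison set hbHep beside liver of FAH mice on NTBC, 3 mice each. Yap1 did not pass (1130 ± 189 and 1265 ± 110, log2 fold change -0.17, SE 0.21, limma adjusted p = 0.548, exact permutation p = 0.5). Ctnnb1 was 1.81-fold higher in hbHep (4670 ± 259 against 2585 ± 167, SE 0.16 on the log2 scale, adjusted p = 0.000583). Fah was 1.81-fold lower (929.4 ± 240 against 1648 ± 154, SE 0.20, adjusted p = 0.0039). The exact permutation p of both was 0.1, the smallest that 3 against 3 allow. Of 17958 genes 3588 were higher and 3058 lower, 2288 and 979 by at least 2-fold; with only these 2 groups in the model the counts were 2259 and 1798.

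Pericentral genes were high and periportal genes low in hbHep. Of 24 beta-catenin and pericentral genes 20 rose and 2 fell, Ces1d (-2.66) and Cyp2c29 (-1.50), also adjusted over the list alone (median log2 fold change 2.75, p = 1.71e-14, adjusted p = 0.207 with an estimated correlation). Nkd1, a beta-catenin target that restrains the pathway, was 9633 ± 5810 against 270.1 ± 35 (n = 3 each, SE 0.43, adjusted p = 7.85e-07). Oat was 144500 against 5282 ± 1360 (SE 0.30, adjusted p = 1.88e-08) and Rhbg 11810 against 498.8 ± 69.2 (SE 0.27, adjusted p = 1.13e-08). Glul was 63680 ± 20900 against 4894 ± 836, and Axin2 (3.73) and Lgr5 (3.12) rose. Cyp2e1 was 172700 ± 64600 against 136700 ± 29000 and did not pass (adjusted p = 0.595). It passed under quantile normalization (log2 fold change 1.292, adjusted p = 0.00553). All 20 periportal genes fell (20 adjusted over the list alone, median -2.63, p = 1.71e-14, adjusted p = 0.207 with an estimated correlation). Cps1 (ENSMUSG00000025991, chromosome 1, 67122426 to 67231267), the first enzyme of the urea cycle, was 55530 ± 17800 against 285400 ± 7330 (SE 0.35, adjusted p = 6.76e-05). Cyp2f2 (ENSMUSG00000052974, chromosome 7, 27119955 to 27133660) was 1612 ± 1510 against 22560 ± 2170 (SE 0.56, adjusted p = 3.65e-05), the sulfotransferase Sult5a1 24.59 against 624.2 and Mup20 1039 against 41460. The urea cycle list split into 3 that rose, Oat, Rhbg and Glul, and 8 of the other 10 that fell, with Arg1 at -3.55 and Otc at -3.11 (3 and 8 adjusted over the list alone, p = 0.0289, adjusted p = 0.469 with an estimated correlation). Its call was lost with only the 2 groups (adjusted p = 0.0572) and under quantile normalization (adjusted p = 0.486).

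Major urinary proteins took the largest falls. Mup1 (ENSMUSG00000078683, chromosome 4, 60498012 to 60501960) was 3088 ± 3590 in hbHep and 615300 ± 193000 in FAH liver (log2 fold change -8.35, SE 0.68, adjusted p = 3.44e-07). Mup19 was 24.35 against 5489, Mup7 194.9 against 90480, Mup12 11.86 against 2552 and Mup11 52.28 against 7248. Secreted proteins fell in 20 of 27 and rose in 0 (22 and 1 adjusted over the list alone, median -1.07, p = 1.68e-07, adjusted p = 0.342 with an estimated correlation). The protease inhibitor Serpina1c was at 6353 against 114000 and Serpina1b at 14490 against 151100. Drug metabolism genes fell in 18 of 32 and rose in 5, with Cyp2b10 at -5.12 and Cyp1a2 at 1.76 (18 and 5 adjusted over the list alone, p = 0.000101, adjusted p = 0.393 with an estimated correlation). Bile acid genes fell in 11 of 20 and rose in 3, with Cyp7b1 at -3.82 and Slco1b2 at 0.90 (11 and 4 adjusted over the list alone, p = 0.000542, adjusted p = 0.391 with an estimated correlation). Fatty acid oxidation genes fell in 9 of 20 with 3 higher (10 and 3 adjusted over the list alone, p = 0.00546, adjusted p = 0.503 with an estimated correlation). Transcription factors fell in 9 of 22 and rose in 2, with Onecut1 at -2.11 (10 and 2 adjusted over the list alone, p = 0.00143, adjusted p = 0.409 with an estimated correlation). Gluconeogenesis genes fell in 9 of 15 (9 adjusted over the list alone, p = 5.27e-05, adjusted p = 0.296 with an estimated correlation). ER stress genes fell in 11 of 19 with Atf3, Asns and Ddit3 higher (12 and 4 adjusted over the list alone, p = 0.00809, adjusted p = 0.428 with an estimated correlation). Quantile normalization ended the calls of drug metabolism (adjusted p = 0.191), bile acid genes (adjusted p = 0.112), fatty acid oxidation (adjusted p = 0.974), transcription factors (adjusted p = 0.102) and ER stress genes (adjusted p = 0.123).

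Tyrosine catabolism fell in 5 of 12 genes, with Gnmt at -1.24 (5 adjusted over the list alone, median log2 fold change -0.52, p = 0.0202, adjusted p = 0.473 with an estimated correlation). Ribosomal protein genes fell in 2 of 25 (1 adjusted over the list alone, median -0.37, p = 0.0043, adjusted p = 0.624 with an estimated correlation). Quantile normalization turned both medians, to 0.008 and 0.03. The tyrosine call was also lost without hbHep mouse 2 (adjusted p = 0.0595) or FAH liver 1 (adjusted p = 0.0671), and the ribosomal call without FAH liver 1 (adjusted p = 0.0644) and with fry (adjusted p = 0.145). Sex-biased genes fell in 8 of 20 and rose in 3, with Hsd3b5 at -5.55 and Sult2a1 at 4.65 (8 and 4 adjusted over the list alone, p = 0.0386, adjusted p = 0.296 with an estimated correlation). Clock genes fell in 6 of 19 and rose in 2, with Ciart at -1.83 and Npas2 at 2.16 (6 and 2 adjusted over the list alone, p = 0.0173, adjusted p = 0.335 with an estimated correlation). The sex-biased call was lost without hbHep mouse 2 (adjusted p = 0.0619) or FAH liver 2 (adjusted p = 0.0761), with a smaller pseudocount (adjusted p = 0.0569) and under quantile normalization (adjusted p = 0.0631). The clock call ended without hbHep mouse 2 (adjusted p = 0.0582) and under quantile normalization (adjusted p = 0.065).

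Mitosis, interferon response, cholesterol synthesis and fetal genes were higher in hbHep than in FAH liver. All 26 mitosis genes rose (26 adjusted over the list alone, median log2 fold change 2.04, p = 1.6e-14, adjusted p = 0.207 with an estimated correlation). Mki67 was at 747.2 ± 164 against 69.22 ± 13.8 (SE 0.30, adjusted p = 7.89e-07), the kinase Plk1 at 48.55 against 6.787 and Ccnb1 at 150.4 against 22.35. Interferon response genes rose in 23 of 26 and fell in 0 (24 and 1 adjusted over the list alone, median 1.92, p = 3.05e-13, adjusted p = 0.207 with an estimated correlation). Usp18, a negative regulator of interferon signaling, was at 1242 ± 318 against 58.18 ± 6.43 (SE 0.16, adjusted p = 1.04e-10), the RNA sensor Oas1a at 402.4 against 31.46 and Oasl1 at 216.4 against 17.61. Cholesterol synthesis rose in 16 of 20, Hmgcs1 by 3.00 (16 adjusted over the list alone, p = 3.87e-07, adjusted p = 0.342 with an estimated correlation). YAP1 targets rose in 13 of 25 and fell in 2, with Areg at 4.49, Ankrd1 at 2.70 and Ccn2 at 0.29, which did not pass (13 and 2 adjusted over the list alone, p = 0.00048, adjusted p = 0.25 with an estimated correlation). Fetal genes rose in 11 of 21 and fell in 2 (13 and 2 adjusted over the list alone, p = 0.000433, adjusted p = 0.207 with an estimated correlation). Igf2 was 4999 ± 3960 against 27.28 ± 15.6 (SE 0.58, adjusted p = 2.64e-07), while Afp ranged from 966.4 to 19030 among the 3 hbHep mice against 141.7 ± 24.4. Cholangiocyte genes rose in 12 of 23 and Onecut1 fell (13 and 1 adjusted over the list alone, p = 0.00144, adjusted p = 0.384 with an estimated correlation), with Prom1 at 3.39 and Cldn4 at 3.33. Largest of all by the rule were Duoxa1 (1812 ± 644 against 4.577 ± 2.51, log2 fold change 8.39, SE 0.45), Myot (360.7 against 1.018), Duox1, an oxidase that makes hydrogen peroxide and partner of Duoxa1 (2460 ± 1230 against 11.94 ± 3.58), Igf2 and the acyltransferase Mogat2 (1205 against 7.49).

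Markers of macrophages and lymphocytes were higher as well in hbHep. Macrophage markers rose in 14 of 21 and Cd163 fell, with Gpnmb at 5.42 and Marco at 3.62 (15 and 1 adjusted over the list alone, p = 5.73e-05, adjusted p = 0.392 with an estimated correlation). T, NK and B cell markers rose in 13 of 20 and Ighm fell, with Jchain at 3.05 and Gzma at 2.86 (13 and 1 adjusted over the list alone, p = 0.000125, adjusted p = 0.25 with an estimated correlation). p53 targets rose in 9 of 20 and fell in 2, with Cdkn2a at 3.31 and Cdkn1a at 2.77 (9 and 2 adjusted over the list alone, p = 0.0114, adjusted p = 0.391 with an estimated correlation). Their call was lost without hbHep mouse 2 (adjusted p = 0.0582). Glycolysis genes (adjusted p = 0.0893), S phase genes (adjusted p = 0.307), NRF2 genes (adjusted p = 0.399, median -0.07, mean 0.50) and acute phase genes (adjusted p = 0.155) did not pass. The same held for neutrophil markers (adjusted p = 0.0668), endothelial markers (adjusted p = 0.116), matrix genes (adjusted p = 0.0894), red blood cell genes (adjusted p = 0.53) and Hippo components (adjusted p = 0.569). Some of these passed under other settings. Glycolysis did so without the filter on low values (adjusted p = 0.0228), under quantile normalization (adjusted p = 0.00675), with fry (adjusted p = 0.0158), without hbHep mouse 3 (adjusted p = 0.0414) and without FAH liver 1 (adjusted p = 0.04). Neutrophil markers passed without the filter (adjusted p = 0.0109), with only the 2 groups (adjusted p = 0.0242) and without hbHep mouse 3 (adjusted p = 0.0436), and matrix genes without the filter (adjusted p = 0.0206) and without hbHep mouse 2 (adjusted p = 0.016). Acute phase genes passed under quantile normalization (adjusted p = 0.023), with fry (adjusted p = 0.00139) and without hbHep mouse 2 (adjusted p = 0.0131). NRF2 genes passed under quantile normalization (adjusted p = 0.00899), endothelial markers, lower in hbHep, without hbHep mouse 1 (adjusted p = 0.00582), and Hippo components with fry (adjusted p = 0.0482).

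**Figure D3:**
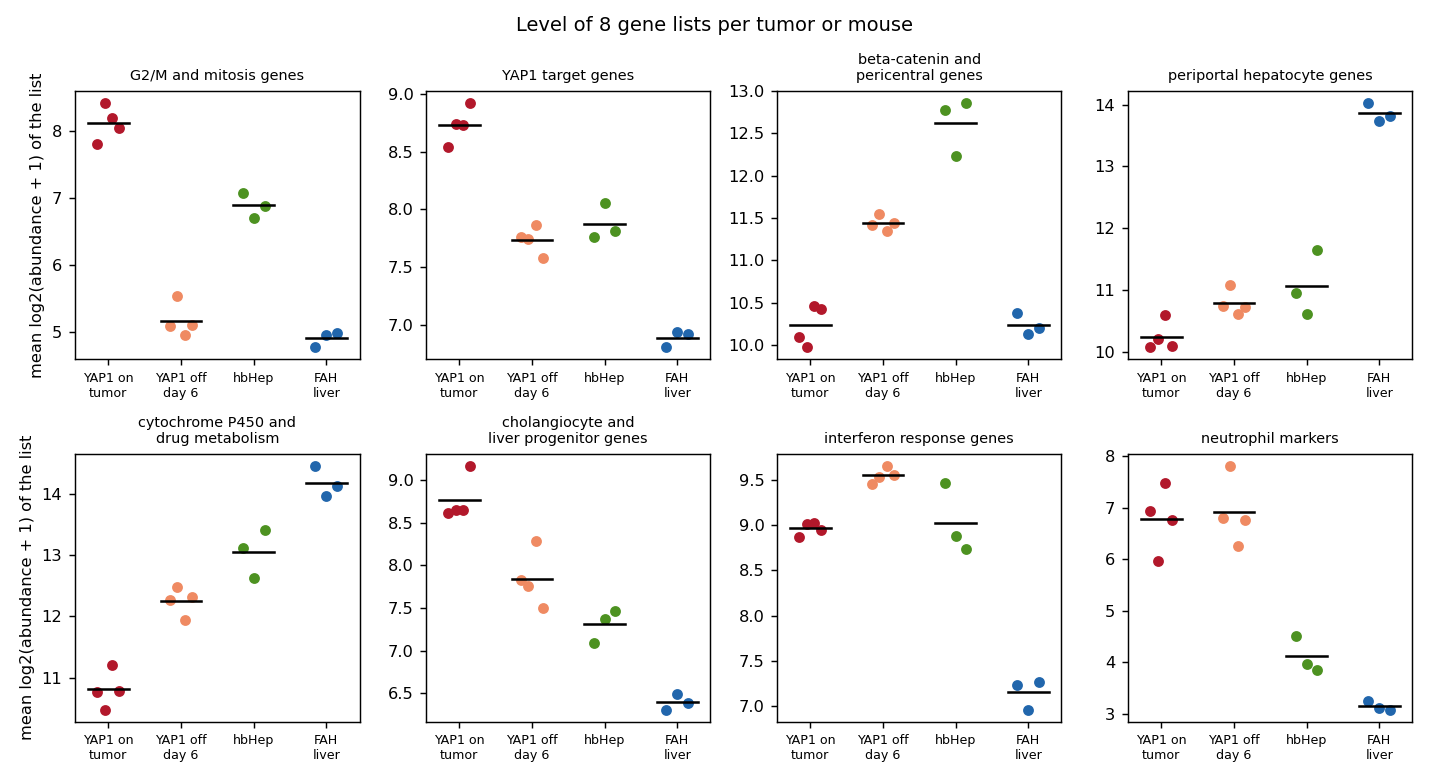
Mean log2(abundance + 1) of the members of 8 gene lists in each tumor or mouse. Mitosis genes average 8.12 in YAP1on tumors, 5.17 at day 6, 6.89 in hbHep and 4.90 in FAH liver, and periportal genes average 10.25, 10.79, 11.07 and 13.86.

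The fourth comparison gave the distance of the tumors from liver. Yap1 was 6.46-fold higher in YAP1on tumors (n = 4) than in FAH liver (n = 3; log2 fold change 2.69, SE 0.19, limma adjusted p = 1.08e-08, exact permutation p = 0.0286). Ctnnb1 was 4.37-fold higher (11440 ± 2100 against 2585 ± 167, adjusted p = 6.77e-09, exact permutation p = 0.0286). Fah did not pass (2097 ± 426 against 1648 ± 154, log2 fold change 0.33, adjusted p = 0.14, exact permutation p = 0.2). It did without YAP1on tumor 1 (log2 fold change 0.488, adjusted p = 0.0195) and under quantile normalization (0.882, adjusted p = 0.000175). Of 17958 genes 6222 were higher and 5987 lower in tumors, 4219 and 3320 by at least 2-fold, across a difference of strain and tissue at once. Here too the 4 YAP1on tumors came from 1 mouse.

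Division, duct, matrix and myeloid genes were higher in tumors. All 26 mitosis genes rose (26 adjusted over the list alone, median log2 fold change 3.18, p = 3.29e-12, adjusted p = 0.207 with an estimated correlation), Mki67 27.5-fold and Ccnb2 17.7-fold. S phase genes rose in 17 of 26 and fell in 4 (17 and 4 adjusted over the list alone, p = 0.0114, adjusted p = 0.473 with an estimated correlation). Cholangiocyte genes rose in 18 of 23 and Krt23 fell (19 and 1 adjusted over the list alone, median 2.82, p = 1.41e-05, adjusted p = 0.287 with an estimated correlation), with Spp1 at 5.86 and Bicc1 at 5.65. YAP1 targets rose in 18 of 25 and fell in 3, with Ankrd1 at 7.60 and Ccn2 at 2.99 (19 and 3 adjusted over the list alone, p = 0.000113, adjusted p = 0.207 with an estimated correlation). Hippo components rose in 13 of 20 with 2 lower (13 and 2 adjusted over the list alone, p = 0.00175, adjusted p = 0.28 with an estimated correlation). All 13 neutrophil markers rose, Ngp by 5.92 (13 adjusted over the list alone, median 3.70, p = 3.11e-05, adjusted p = 0.296 with an estimated correlation). Macrophage markers rose in 18 of 21, Ms4a7 by 6.08, with Cd163 lower (18 and 1 adjusted over the list alone, p = 1.07e-05, adjusted p = 0.367 with an estimated correlation). Matrix genes rose in 19 of 25, Timp1 by 4.53 (19 adjusted over the list alone, p = 7.43e-06, adjusted p = 0.322 with an estimated correlation). T, NK and B cell markers rose in 17 of 20, Nkg7 by 3.23 (18 adjusted over the list alone, p = 0.000906, adjusted p = 0.289 with an estimated correlation). Interferon response genes rose in 21 of 26 and fell in 0 (21 adjusted over the list alone, median 1.98, p = 2.05e-06, adjusted p = 0.296 with an estimated correlation). Oas1a stood at 582.1 against 31.46, Ifi44 at 317.5 against 28.44 and Ifit2 at 825.8 against 77.07. Fgfbp1, which carries growth factors out of the matrix, was 2425 ± 659 against 0.5168 (SE 0.35, adjusted p = 4.64e-12). Gvin1 and Hist1h4m, at 1837 and 788.2 in tumors, were listed at 0 in the 3 liver libraries.

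Most hepatocyte lists were lower in tumors. Drug metabolism genes fell in 29 of 32 and Sult1a1 rose (29 and 1 adjusted over the list alone, median log2 fold change -2.90, p = 5.13e-11, adjusted p = 0.25 with an estimated correlation). Cyp2f2 stood at 140.7 against 22560 (SE 0.52, adjusted p = 7.47e-09), Ces3a at 173.4 against 26480, Cyp7b1 at 157.5 against 26780 and Cyp3a11, its most abundant member, at 18280 against 293900. Bile acid genes fell in 18 of 20 (18 adjusted over the list alone, median -2.11, p = 1.65e-08, adjusted p = 0.25 with an estimated correlation). The organic anion transporter Slco1a1 was at 83.72 against 9068, Cyp8b1 at 735.1 against 17240 and Abcb11 at 7115 against 28080. Periportal genes fell in 18 of 20 (18 adjusted over the list alone, median -3.79, p = 3.45e-08, adjusted p = 0.24 with an estimated correlation). The lyase Etnppl was at 127.1 against 11840, the serine dehydratase Sds at 332.6 against 11180 and Cps1 at 41120 ± 11500 against 285400 ± 7330. Mup7 was listed at 0 in the 4 tumors and at 90480 ± 55100 in liver, Mup17 was 0.2491 against 275000, Mup9 3.62 against 759100 and Mup1 2.887 against 615300. Urea cycle genes fell in 10 of 13 (10 adjusted over the list alone, p = 6.38e-05, adjusted p = 0.28 with an estimated correlation). Tyrosine catabolism fell in 11 of 12 (11 adjusted over the list alone, p = 8.16e-05, adjusted p = 0.296 with an estimated correlation). Gluconeogenesis fell in 13 of 15 (13 adjusted over the list alone, p = 0.000268, adjusted p = 0.322 with an estimated correlation). Fatty acid oxidation fell in 17 of 20 with 2 higher (17 and 2 adjusted over the list alone, p = 3.88e-06, adjusted p = 0.322 with an estimated correlation). Secreted proteins fell in 18 of 27 (18 adjusted over the list alone, p = 0.000188, adjusted p = 0.466 with an estimated correlation). Transcription factors fell in 16 of 22, with Nr1i3 at -5.13, and rose in 2 (16 and 2 adjusted over the list alone, p = 0.000244, adjusted p = 0.367 with an estimated correlation).

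NRF2 genes fell in 16 of 22 and Hmox1 rose (16 and 1 adjusted over the list alone, p = 0.000203, adjusted p = 0.423 with an estimated correlation). ER stress genes fell in 16 of 19 and Atf3 rose (16 and 1 adjusted over the list alone, p = 0.000506, adjusted p = 0.335 with an estimated correlation). Sex-biased genes fell in 12 of 20 and rose in 5 (12 and 5 adjusted over the list alone, p = 0.00942, adjusted p = 0.25 with an estimated correlation). Male-biased Elovl3 was at -9.32, Y-linked Eif2s3y at -8.15 and female-biased Cyp2b9 at 7.03. Pericentral genes did not move one way (8 of 24 higher, 7 lower, 8 and 7 adjusted over the list alone, adjusted p = 0.492, median log2 fold change 0.22, mean 0.00). The beta-catenin targets Axin2 (2.78) and Tnfrsf19 (3.46) were higher and Cyp2c29 (-4.62) and Cyp1a2 (-3.38) lower. Nor did fetal genes pass (10 of 21 higher, 3 lower, 10 and 3 adjusted over the list alone, adjusted p = 0.0634), with Gpc3 at 5.98, Igf2bp1 at 4.41 and Bex1 at 4.21. Afp (-0.27) and Igf2 (0.34) did not pass. The list passed without YAP1on tumor 2 (adjusted p = 0.0384), without the filter on low values (adjusted p = 0.0272), with values as deposited (adjusted p = 0.0458) and with fry (adjusted p = 1.75e-05). Also without a call were glycolysis (adjusted p = 0.79), cholesterol synthesis (adjusted p = 0.973), p53 targets (adjusted p = 0.296), acute phase genes (adjusted p = 0.138) and endothelial markers (adjusted p = 0.674). The last were red blood cell genes (adjusted p = 0.222), clock genes (adjusted p = 0.289) and ribosomal protein genes (adjusted p = 0.649, median -0.25, mean 0.03). Quantile normalization turned the ribosomal median to 0.857. Acute phase genes passed under it (adjusted p = 0.00321), without the filter (adjusted p = 0.0487) and with fry (adjusted p = 9.28e-05), and cholesterol synthesis under it alone (adjusted p = 0.0442). With fry p53 targets (adjusted p = 0.00478), red blood cell genes (adjusted p = 0.0215) and clock genes (adjusted p = 0.00169) passed. Quantile normalization also ended the calls of secreted proteins (adjusted p = 0.916), gluconeogenesis (adjusted p = 0.121), S phase genes (adjusted p = 0.123) and ER stress genes (adjusted p = 0.0766).

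Genes that changed at day 6 often differed the same way between liver and tumor. Of the 2296 genes higher at day 6, 1698 (74%) were also higher in FAH liver than in YAP1on tumors and 230 lower, where independent lists would share 765 and 796. Of the 1952 genes lower at day 6, 1528 (78.3%) were also lower in liver and 135 higher, against 676 and 651. For hbHep the shared counts were 4180 of 5155 higher genes and 3857 of 4751 lower genes, against 1719 and 1646. All of these comparisons share the YAP1on tumors. Across genes the fold changes of day 6 and of liver correlated at 0.49, and unchanged groups set against the same tumors gave 0.46 on average in 20 simulations, but the covariance was 0.678 against 0.046. With the 4 YAP1on tumors split into pairs, 1 pair for each comparison, the covariance was 0.64 to 0.649. All 4 come from 1 mouse, so neither the simulation nor the split removes what the comparisons share through that mouse. For hbHep and liver, which also share the strain background, the correlation was 0.80 against 0.43 in the simulations, and the covariance 1.939 against 0.046, or 1.901 to 1.91 with the tumors split.

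The ATAC libraries asked how accessible DNA moved over 64 days without YAP1, with 1 library per time and no replicates, so the values describe these libraries. The lists held 1023760 intervals at day 14, 780497 at day 33, 769500 at day 64 and 571520 in liver, covering 71.7, 57.5, 55.8 and 36.7 Mb with median widths of 67, 71, 70 and 61 bp. The YAP1on list held 829850 short intervals without overlaps that covered 19.7 Mb (median width 21 bp). Its layout differs, so it was not compared with the others in level. The Jaccard index was 0.506 for days 14 and 33, 0.565 for days 33 and 64, and 0.467 for days 14 and 64. With liver it was 0.36 at day 14, 0.443 at day 33 and 0.437 at day 64. These values depend on the number of intervals: with equal numbers they were 0.281, 0.369 and 0.266 between days, in the same order, and 0.267, 0.371 and 0.368 with liver, so day 33 was then as close to liver as to day 64. Of the intervals at day 14, 47.4% overlapped a liver interval, against 6.62% after moving them by 100 kb; at days 33 and 64 it was 61.1% (6.48% moved) and 60.8% (6.35% moved).

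**Figure D4:**
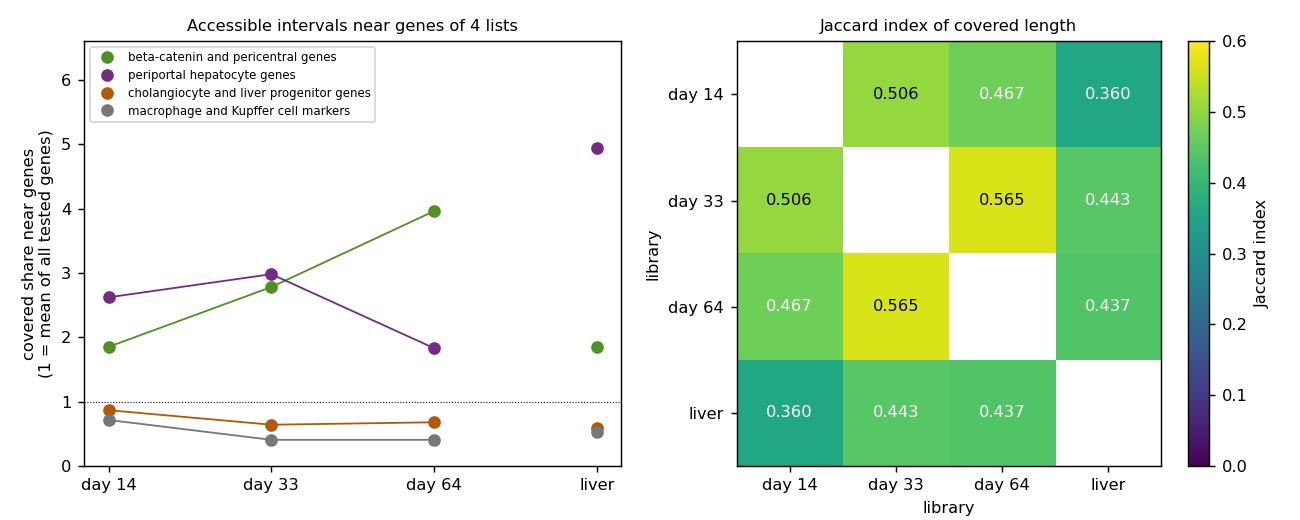
Left, covered share near the genes of 4 lists (gene and 10 kb on each side, relative to the mean of all tested genes, dotted line at 1) at days 14, 33 and 64 without YAP1 and in liver, 1 library each. Right, Jaccard index of covered length between these 4 libraries. The pericentral list climbs from 1.85 at day 14 to 3.96 at day 64, above its 1.85 in liver, and the periportal list ends at 1.83 against 4.94 in liver.

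Chromatin near zonal genes differed between day 64 and liver. The covered share near the 24 pericentral genes was 1.85 times the mean of all tested genes at day 14, 2.78 times at day 33, 3.96 times at day 64 and 1.85 times in liver (percentiles 83.3, 100, 100 and 82 among matched random lists). Of these genes 24 of 24 were higher at day 64 than in liver, beside 43% of all genes. Near Axin2, a negative feedback gene of the pathway, it was 1.46, 2.65, 5.60 and 0.841 in the same order. For the 20 periportal genes the share was 2.62, 2.98, 1.83 and 4.94, with 18 of 20 lower at day 64 than in liver (14 without scaling to the library). Without scaling each ratio to liver was 1.99 times as large at day 14, 1.54 times at day 33 and 1.49 times at day 64, and 21, 18 and 18 of 32 lists turned from below to above liver, the periportal list at day 14 (1.05) among them. Near Cps1 it went from 7.30 at day 14 and 6.28 at day 33 to 0.658 at day 64, beside 10 in liver (unscaled, day 14 was 1.45 times liver). Near cholangiocyte genes the share was 0.865, 0.639, 0.677 and 0.586, and near macrophage markers 0.713, 0.404, 0.404 and 0.53; unscaled, macrophage markers were above liver at days 33 and 64 too (1.18 and 1.13 times).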

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

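Single samples far from the other 3 of their group were looked for with Dixon's test in 96 groups of 4 tumors (named genes in the 2 tumor groups), and it singled out 10, of which 9 are given below. Chance flags about 1 in 20 groups, so part of these 10 can be chance, and groups of 3 mice were not checked.

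YAP1on tumor 1 was low for 3 hepatocyte genes. Fah was 1470 there and 2226 to 2416 in the other 3 tumors, the bile acid hydroxylase Cyp8b1 240.2 beside 847.2 to 1004, and the urea cycle enzyme Cps1 24190 beside 43430 to 48910. Mup10 was 1.096 in the same tumor and listed at 0 in the others. Fah passed between YAP1on tumors and FAH liver without this tumor (log2 fold change 0.488, adjusted p = 0.0195) and not with it. No biological explanation was tested, since the labels name no difference among the 4 tumors.

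Day 6 tumor 2 was high for 3 cell division genes. The cyclin Ccnb2 was 45.49 there and 20.22 to 21.03 in the other 3, the helicase subunit Mcm5 173 beside 113.7 to 116.9, and the replication licensing factor Cdc6 58.24 beside 13.05 to 16.63. All 3 stayed below every YAP1on tumor. Without this tumor 1756 genes were higher at day 6, beside 2296 with it. Here too no biological explanation was tested.

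YAP1on tumor 3 held the last 2 values. The major urinary protein gene Mup17 was 0.9962 there and listed at 0 in the other 3, near the lowest values in the table, and the organic anion transporter Slco1a1 was 125 beside 68.55 to 71.04. The level of Slco1a1 in this tumor remained far below the 9068 of FAH liver.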

How the results depend on the processing

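Alternatives chosen only after the data were seen were those of the covered share near genes (surroundings of 2 kb, equal numbers of intervals, no scaling to the library) and the simulation and split of the YAP1on tumors for hbHep and liver. With a fold of at least 2 asked for, higher and lower genes were 795 and 949 for day 6 against YAP1on tumors, 2516 and 2516 for hbHep against YAP1on tumors and 2288 and 979 for hbHep against FAH liver, and lower genes of YAP1on tumors against FAH liver were 3320. With only the 2 groups in the model, hbHep against FAH liver gave 2259 and 1798.

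No list passed camera with an estimated correlation, and fry passed 23, 22, 25 and 27. Quantile normalization passed 20, 19, 16 and 21 lists and turned 3 medians: tyrosine catabolism in hbHep against FAH liver (0.008, adjusted p = 0.537), ribosomal protein genes in the same comparison (0.03, adjusted p = 0.81) and ribosomal protein genes in YAP1on tumors against FAH liver (0.857, adjusted p = 8.2e-05); the cause was not tested. Over 128 list results and 2432 values, 2264 gave the same call, 128 were weaker, 37 stronger and 3 reversed. Of the weaker ones 90 came from the estimated correlation, 20 from quantile normalization and 12 from leaving out 1 replicate. Over 120 results of named genes and 2040 values, 2034 gave the same call, 3 were weaker and 3 stronger (Cyp2e1, and Fah under 2 settings).

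Leaving out 1 replicate gave 1756 to 2109 higher and 1523 to 1834 lower genes for day 6 against YAP1on tumors, and 23 to 25 lists. For hbHep against YAP1on tumors it gave 4665 to 4975, 4129 to 4515 and 19 to 21 lists, for hbHep against FAH liver 3198 to 3476, 2271 to 3004 and 21 to 25, and for YAP1on tumors against FAH liver 5801 to 6094, 5593 to 5950 and 22 to 23.

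Replicate numbers do not pair the samples: deviations of samples with the same number correlated at -0.23 to 0.19. With the number as a block, higher and lower genes were 1965 and 1739, 4818 and 4331, 3337 and 2670, and 5870 and 5738, with 25, 20, 23 and 22 lists, and no call of a list or a named gene changed.

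In ATAC, intervals of at least 200 bp left 0, 14014, 13142, 12370 and 5834 (YAP1on, days 14, 33 and 64, liver), covering 0.0, 3.5, 3.32, 3.1 and 1.43 Mb, so the intervals reported were mostly short. With the same number of intervals from each library, the Jaccard index of the YAP1on list with days 14, 33, 64 and liver was 0.108, 0.117, 0.114 and 0.129; it was 0.281 for days 14 and 33, 0.266 for days 14 and 64, 0.369 for days 33 and 64, and 0.267, 0.371 and 0.368 for days 14, 33 and 64 with liver. Asking for an overlap of at least 50% of the interval gave 67.8, 57.8, 55.1 and 41.9% for the YAP1on list in days 14, 33, 64 and liver, and 34.8, 46.5 and 46.9% for days 14, 33 and 64 in liver. Equal numbers gave 43.1, 47.7 and 46.2% for the YAP1on list in days 14, 33 and 64, and 47.3% for day 14 in liver. Windows of 2.5 kb raised neutrophil markers with an interval at day 33 from 2 to 4, and 159 of 160 list counts stayed within 1.5 times. Without scaling to the library, the covered share of the periportal list at day 14 over liver was 1.05, beside 0.529 scaled, and at day 33 0.93, beside 0.603. For the pericentral list it was 1.99 at day 14 and 2.32 at day 33, beside 1.0 and 1.5. It turned the urea cycle list at days 14 and 33 from 0.634 and 0.76 to 1.26 and 1.17, NRF2 genes from 0.845 and 0.999 to 1.68 and 1.54, macrophage markers at days 33 and 64 from 0.763 and 0.761 to 1.18 and 1.13, and fatty acid oxidation at day 64 over day 14 from 1.31 to 0.981. Keeping only the intervals with values above the median was not run, since no value could be compared between the lists.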

Other observations

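The tests of mixed tissue, of origin and of zonal chromatin below were chosen only after the results were seen; the count of mice per group and the other splits of the samples were planned. Chromatin near other metabolic genes differed between lists, in 1 library per time. The covered share near NRF2 genes was 1.35 at day 14, 1.60 at day 33, 2.15 at day 64 and 1.60 in liver, and 15 of 22 genes were higher at day 64 than in liver (22 without scaling to the library). Near genes of fatty acid oxidation it was 2.46, 2.88, 3.23 and 2.36, near the urea cycle list 3.79, 4.55, 3.21 and 5.98, and near cholesterol synthesis genes 2.58, 2.62, 1.87 and 1.75. Without scaling, the urea cycle list stood above liver at days 14 and 33 (1.26 and 1.17 times), as NRF2 genes did (1.68 and 1.54), and fatty acid oxidation was not higher at day 64 than at day 14 (0.981 times).

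Other splits of the same samples measured what groups drawn by chance can give. For day 6 against YAP1on tumors 1 of 35 splits, the real one, called as many genes (4248, highest other 2), for hbHep against YAP1on tumors 1 of 35 (9906, highest other 5221), and for YAP1on tumors against FAH liver 1 of 35 (12209, highest other 8102), so tumors grouped by chance are excluded in these 3. Tumors of a group share 1 mouse, so the splits do not exclude chance differences between mice. For hbHep against FAH liver 1 of 10 splits was as large (6646, highest other 2), and the splits are too few for a share under 0.05.

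Hepatocyte genes rose and mitosis genes fell at day 6, and more normal liver in the day 6 samples could give part of this. Taking FAH liver as the liver mixed in, it is excluded for most cholesterol synthesis and pericentral genes: 16 of the 19 and 10 of the 16 that rose lay in every day 6 tumor above every YAP1on tumor and every liver, where no mixture can lie (0 to 3 in each of 9 other hepatocyte lists); nor does it explain genes that need a liver share above 25%, among them 9 of 12 tyrosine catabolism genes and 5 of 11 secreted proteins that rose, since 18 of the 50 most abundant liver transcripts (23 unfiltered) stayed below 25% of liver in every day 6 tumor. With FAH liver it is excluded as the cause of the mitosis fall, which would need a share of 87.2%. Mitosis genes kept a median of 12.8% of YAP1on, the 50 most abundant tumor-high transcripts 60.7% (quartiles 45.8 to 86.7, 61.5% unfiltered). Leaving out cell cycle and YAP1 target lists removed 0 of the 50. A first test (1 of 50 transcripts implied such a share, Nat8f2 at 112%) had left this open. Liver of the tumor mice, which may hold more of the 50, was not tested. For hepatocyte genes that need less, admixed liver can be neither excluded nor shown, as the verdict turns on a filter chosen after the first value was seen. Over the same 50 liver transcripts the 10th percentile of the implied liver share was 2.36% (median 12.1%, 90th percentile 42.5%, 4 at or below 0, Alb at -8.59%) without unnamed transcripts. With them it was -0.0757% (9 of 50). Each group came from 1 mouse, so a difference between the 2 mice cannot be told apart from the loss of YAP1, which stays a hypothesis for both changes.

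Transcripts that marked the tumors were nearly missing in hbHep, and Y-linked ones were present. The 9 transcripts seen in tumors only had a median of 0.259% of their tumor level in hbHep (0.0228 to 22.7%), 22 seen in liver only had a median of 78.6% of liver, and 4 Y-linked ones 74.1% (tumors 4.13%). This is consistent with hbHep cells of another strain or sex than the sequenced tumors, but host liver cells would carry the same transcripts. Samples made mostly of unaltered host liver are excluded by the 50 most abundant liver transcripts, here taken whatever their level in tumors. Mup, sex-biased and Y-linked genes were again left out. Of these, 16 were below 50% of liver in every hbHep mouse (14 with unnamed transcripts kept), with Cps1 at 19.5% and Ttr at 29.6%. Host hepatocytes altered by their surroundings stay open, and so do sex and strain, which were not tested apart from the tumor state; reads over the deleted exon of Fah would decide.

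Pericentral genes had more and periportal genes less covered sequence at day 64 than in liver, as the RNA of hbHep had more and less of their transcripts. A few genes do not decide the pericentral difference, since 24 of 24 genes were higher with and without scaling. For the periportal one this stays open, since 18 of 20 genes were lower but 14 without scaling. The larger covered length at day 64 does not explain both. The periportal share was 0.55 of liver even without scaling (0.37 scaled), and the pericentral 3.19 (2.14 scaled). With 1 library per time, and the rule that made the intervals unknown, a difference between single mice or preparations stays open. A candidate explanation is that tumor cells without YAP1 keep beta-catenin signaling and so a pericentral program. Replicated ATAC with a beta-catenin inhibitor could test it.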
